A study of Caenorhabditis elegans with 12 samples.

How the data were processed

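The samples were 12 total RNA samples of Caenorhabditis elegans, each labelled with Cy3 and hybridised to its own single-colour NimbleGen expression array, 1 array for each of 3 strains and 4 conditions. Groups were taken from the condition named in each sample's labels, and the strain (N2, LS292 dys-1(cx18) or MT4930 ced-1(n1995)) served as the replicate number within a condition. Per the labels, the design held repeats of technique and none of the sample, so strain and array cannot be separated within a condition. No slide, scan or batch information was given in the sources used here.

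The deposited per-array files hold 1 linear intensity for each of 23187 transcript features, already normalized by the authors with RMA per the submitters' processing notes, with the version not given in the sources used here. RMA corrects background, makes the distributions of probe signals alike between arrays and summarises probes, so a change in total RNA per worm is not visible in these values. Of the features, 23148 were summarised from 5 or 6 probes and 39 from fewer. Intensities ran from 39.8 to 59366.3, with no background or detection flag in the files, so a low value cannot be called absent. The series value table held the deposited intensity of 18185 of the same features, with a largest difference of 1.3e-06 on the log2 scale from the per-array files. The 5002 features outside that table were dim, with a median of their highest intensity of 127.9 against 679.6 in it.

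From the authors' deposited intensity, log2 values were computed with no pseudocount and averaged over the features of a gene, giving 20018 genes by WormBase identifier, 2273 of them with more than 1 feature. Gene symbols came from the reference gene table by sequence name for 19428 genes and from the array file for the other 590. No reference genome was used, so no coordinates are given. Near-identical genes, such as the msp- family, can share probe signal, and their single values are uncertain.

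Every gene was fitted with limma 3.58.1 in R 4.3.3, with condition and strain as factors over all 12 arrays (6 residual degrees of freedom, prior degrees of freedom 7.71). The comparisons were static flight against ground control, static against centrifuged flight, centrifuged flight against ground control, ground against transport control, the flown pair against the control pair, any difference among conditions, and each mutant against the wild type. A further fit tested strain by flight interactions. P-values were adjusted by the Benjamini-Hochberg method over 20018 genes, and a gene passed at an adjusted p under 0.05. The pairing of arrays by strain comes from the labels, since arrays with the same replicate number hold the same strain. Pairs of arrays of the same strain and different conditions had a mean correlation of 0.938, against 0.931 for pairs that shared neither and 0.953 for pairs of the same condition.

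A set of 25 gene lists was fixed before the data were examined, as were the designs, the rule for named genes and most alternatives. The lists were DNA damage checkpoint and repair, apoptosis and corpse engulfment, muscle sarcomere, the dystrophin complex, heat shock, oxidative stress, xenobiotic detoxification, insulin and dauer signalling, dauer markers, the TGF-beta body size pathway, vitellogenins, sperm, oocyte and germline, cuticle collagens, moulting, ribosomal proteins, the respiratory chain, fasting and lipid metabolism, innate immunity, neuropeptides, neurotransmission, histones, cell cycle and replication, autophagy and lysosome, and hypoxia. Each was tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, with adjustment over 225 tests of list and comparison. camera made 105 calls, of which none held with an estimated correlation.

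The genes named were the 10 largest rises and 10 largest falls among genes that passed with the same sign in every strain. Where a numbered family held more than 3 of those places, 3 were named and the others counted. Where fewer than 5 genes passed in a direction, the 5 with the smallest p and the same sign in every strain were named as values. Up to 4 members of a list could be named, those that passed with the largest change or otherwise those with the largest change. Within each strain, the 5 largest rises and falls of static flight against ground control were taken, with no test. dys-1 and ced-1 were always considered.

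The steps were tested on simulated data with the real means and spread, with 200 of 20018 genes changed. At 2-fold and 4-fold, static flight against ground control recovered 29% and 85% of changed genes, static against centrifuged flight 30% and 91%, centrifuged flight against ground control 32% and 91%, ground against transport control 23% and 84%, the flown against the control pair 61% and 97%, dys-1 against wild type 46% and 93% and ced-1 against wild type 47% and 94%. The interactions recovered 0% of changed genes at 2-fold, and 4% for dys-1 and 20% for ced-1 at 4-fold.

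Alternatives were array weights, each array, strain or condition left out, only the compared conditions in the fit, no strain factor, no variance moderation, a trended and robust variance, quantile normalization, median centring, an offset of 50 before the log, the series value table, the dimmest 25% of genes left out, a 2-fold minimum, and 1.5-fold and 3-fold thresholds within strains. Chosen after seeing the data were transcript features one by one, the fit without the transport control, the flown pair against each control alone, and for the mutated genes a permutation within conditions. Correlations of changes were set beside 20 simulated data sets without effects. Regroupings were limited to 100. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.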

Results

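Gene expression was measured on 12 single-colour microarrays of the nematode Caenorhabditis elegans after a space flight. The arrays covered 3 strains under 4 conditions, with 1 array for each strain and condition. The strains were the wild type N2, a dys-1(cx18) mutant, whose gene encodes dystrophin, a protein that links the muscle cytoskeleton to the membrane, and a ced-1(n1995) mutant, whose gene encodes a receptor used in the engulfment of dying cells. Dauer larvae, the stress-resistant resting stage, flew for 16.5 days at 23 °C in a static slot, in microgravity, or in an on-board centrifuge held at 1 g, and were collected 7 h after landing. The measured radiation dose was 1.92 mGy in the static slot and 2.27 mGy in the centrifuge. A ground control unit was run in a static slot 2 days later. The fourth group, named the transport control, was kept in an incubator at the home university and was not transported, and its duration, containers and collection are not stated. Single arrays left out of a fit are named by strain and condition, with SS for static flight, SC for the centrifuge, GC for the ground control and TC for the transport control, so that N2-GC is the wild type in the ground control. Each array gave an intensity for 20018 genes, and the number of arrays limits the precision. Nothing in the labels says that arrays of a condition came from separate cultures beyond their different strains, so p-values measure the spread between these arrays.

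Arrays of a condition were on average slightly more alike than arrays of a strain, with mean correlations of 0.953 and 0.938. The ranges overlapped, at 0.929 to 0.969 and 0.858 to 0.978. The 3 transport control arrays lay at the high end of the first principal component, with scores of 28.3 for the wild type, 77.4 for dys-1 and 56.2 for ced-1. The static flight arrays of ced-1 and the wild type lay at the low end, at −71.0 and −54.4, while that of dys-1 scored 0.8. The ced-1 ground control array had a mean intensity of 902.3, the lowest of the 12, against 1018.9 to 1159.6 on the others. It also lay apart from the others on components 2 and 3, at 39.7 and −42.8.

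**Figure D1:**
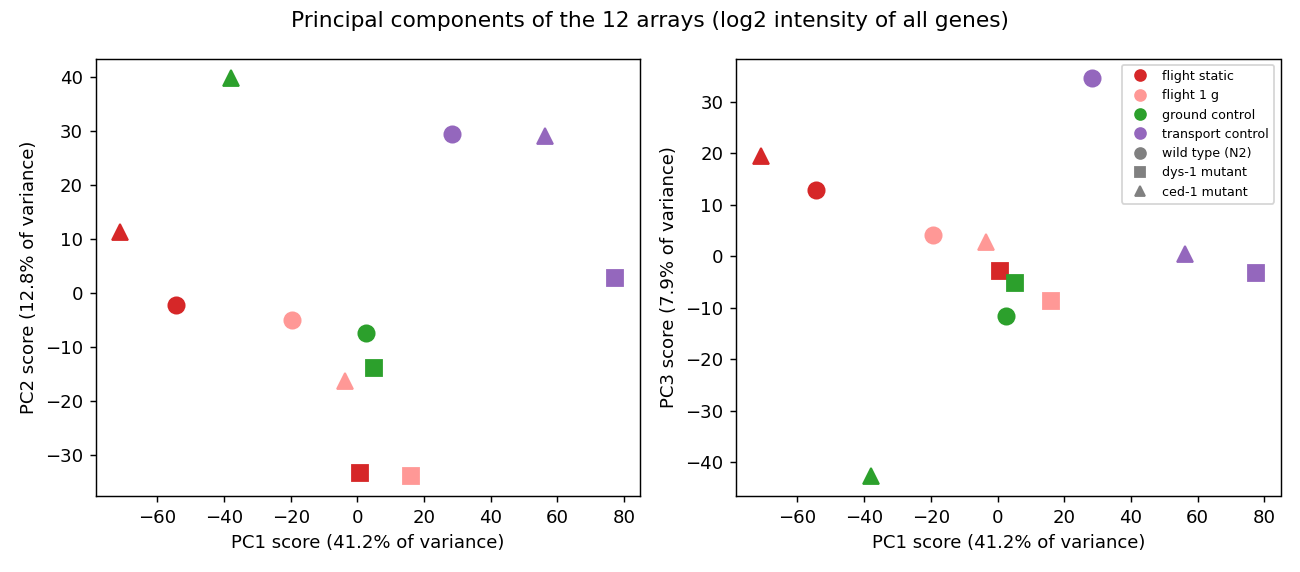
Principal component scores of the 12 arrays (log2 intensity of 20018 genes), component 1 on the x axis of both panels against component 2 (left) and component 3 (right); colour gives the condition, marker shape the strain, and each point is 1 array. Component 1 held 41.2% of the variance, and the transport control arrays lie at 28.3 to 77.4 on it while the ced-1 static flight array lies at −71.0.

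The mutated genes were examined first. The dys-1 transcript had a mean log2 intensity of 7.76 ± 0.65 (SD, n = 4) in the dys-1 mutant and 7.52 ± 0.29 (n = 8) in the other strains. The difference was 0.24 (exact permutation test, two-sided p = 0.416), and it was −0.07 without dys-1-TC (exact permutation p = 0.776). The ced-1 transcript had 9.91 ± 0.30 (n = 4) in the ced-1 mutant against 10.25 ± 0.29 (n = 8) in the others. That difference was −0.34 (exact permutation test, two-sided p = 0.0929), or −0.46 without ced-1-TC (exact permutation p = 0.0424). The ced-1 mutant lay below the mean of the other strains in all 4 conditions, by −0.77 to −0.11. With the mutant array permuted only within conditions, a test added after seeing the data, the exact two-sided p was 0.0494 for ced-1 (0.0988 adjusted over both genes) and 0.309 for dys-1, where 81 assignments allow no p below 0.0123. The labels do not say whether either allele removes its transcript.

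The comparison of static flight with the ground control addresses the whole flight, with microgravity, radiation, launch and landing together. Collagens of the cuticle led the genes that rose. The adult cuticle collagen col-19 rose by 2.21 ± 0.37 log2 units (SE, 3 arrays per condition, 4.61-fold, limma adjusted p = 0.0406). col-143 rose by 2.26 ± 0.37 (adjusted p = 0.0406), col-129 by 2.03 ± 0.27 and col-81 by 1.98 ± 0.27 (both adjusted p = 0.0188), and 6 of the 10 largest rises belonged to col- genes. The largest rise was that of dod-23, a gene acting downstream of the insulin-pathway transcription factor DAF-16, at 2.70 ± 0.36 (6.50-fold, adjusted p = 0.0188). spig-20 rose by 2.01 ± 0.28, vap-2, a venom allergen-like protein, by 1.93 ± 0.32 and C28D4.5 by 1.73 ± 0.32. F26A1.8 fell by 3.89 ± 0.28 (14.8-fold, adjusted p = 3.77e-05). Also lower were dpy-1, which affects body shape, at −1.86 ± 0.25 (adjusted p = 0.0188), Y62H9A.15 at −1.45 ± 0.26 (adjusted p = 0.0442) and grd-13, a hedgehog-related gene, at −1.37 ± 0.22 (adjusted p = 0.0406). nspc-4 was at −1.48 ± 0.29 without passing (adjusted p = 0.0555).

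In all 42 genes passed between static flight and the ground control, 38 higher and 4 lower, each with the same sign in all 3 strains. At an unadjusted p under 0.05 there were 2344 genes, where 1001 are expected by chance. The count was 6 (3 higher, 3 lower) after quantile normalization, 9 (6 higher, 3 lower) after median centring and 116 with an offset of 50. It was 0 by the linear model without variance moderation (2117 at an unadjusted p under 0.05), 1 without the strain factor, 5 with only these conditions in the fit and 2 without the transport control arrays. It was 1 without N2-SS, ced-1-SS or N2-GC. It was 7 without ced-1-GC, dys-1-SC or dys-1-TC, 9 without N2-SC, 16 without ced-1-TC and 18 without ced-1-SC. Of the 14 passing genes named for this comparison, msd-1 and msd-2 of the sperm list included, only F26A1.8 passed with each array left out (highest adjusted p 0.00125). The other 13, collagens and dod-23 among them, were lost without each of N2-SS, ced-1-SS and N2-GC, and each array except N2-TC ended at least 1 call (adjusted p up to 0.381).

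**Figure D2:**
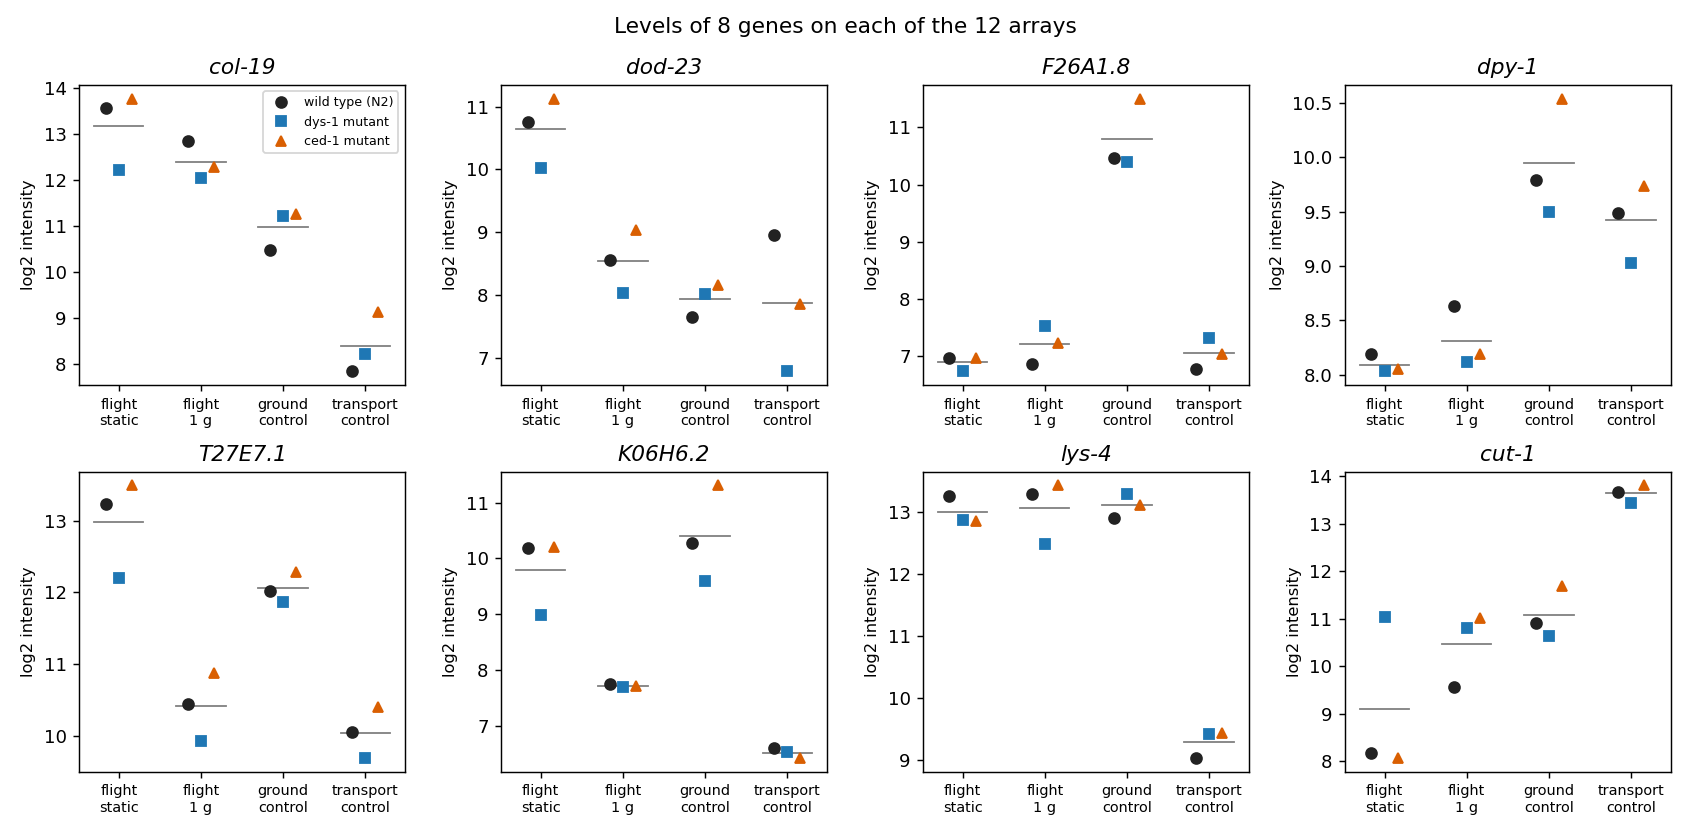
Log2 intensity (y axis) of 8 genes on each of the 12 arrays, by condition (x axis); points are single arrays, marker and colour give the strain, and grey lines are means of 3 arrays. F26A1.8 lies at 10.4 or above in the 3 ground control arrays and at 7.53 or below in the other 9, and col-19 has its highest mean, 13.19, in static flight.

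Germline lists ranked above other genes by camera in static flight against the ground control, while few single genes passed. Of 48 sperm genes, msd-1 rose by 1.38 ± 0.24 (adjusted p = 0.0433) and msd-2, like it a sperm protein, by 1.31 ± 0.23 (adjusted p = 0.0406). So 2 passed over all genes and 9 adjusted over the list alone, with a median of 0.38, and both genes were lost without the arrays just named (adjusted p up to 0.338). msp- genes are near-identical in sequence, so their single values are uncertain. The 41 oocyte, germline and embryo genes had a median of 0.66 (0.39 without N2-GC), with egg-3, an egg activation gene, at 1.39 ± 0.42 and the RNA-binding protein gene puf-3 at 1.17 ± 0.34. The 38 cell cycle and DNA replication genes had a median of 0.60 (0.35 without ced-1-SS), with the kinase gene air-2 at 1.14 ± 0.35 and the cyclin gene cyb-1 at 1.00 ± 0.33. By limma 0 members of these lists passed over all genes or adjusted over the list alone, with 12 and 15 at an unadjusted p under 0.05.

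DNA repair and yolk genes lay in the same direction. The 58 DNA damage checkpoint and repair genes had a median of 0.39, with the mismatch repair gene mlh-1 at 1.11 ± 0.26 (adjusted p = 0.092) and the recombination gene rad-54.L at 1.00 ± 0.23 (adjusted p = 0.0902). By limma, 0 of them passed over all genes and 2 adjusted over the list alone, with 16 at an unadjusted p under 0.05. The 6 vitellogenins, yolk protein genes, had a median of 0.76 (0.49 without N2-GC), with vit-6 at 1.60 ± 0.38 and vit-5 at 1.21 ± 0.28 (both adjusted p = 0.0902). Over all genes 0 passed by limma and 3 passed adjusted over the list alone, with 3 at an unadjusted p under 0.05. camera ranked all 5 lists above other genes, from adjusted p = 0.000354 for the vitellogenins to 1.02e-10 for the sperm genes. None held with the estimate: adjusted p = 0.613 with an estimated correlation for the oocyte genes, adjusted p = 0.595 with an estimated correlation for the cell cycle genes and adjusted p = 0.592 with an estimated correlation for the other 3.

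Neuropeptide and histone lists lay lower in static flight than in the ground control over the 3 strains together. The 107 neuropeptide genes had a median of −0.35, which was −0.89 in the wild type, 0.17 in dys-1 and −0.49 in ced-1, and nlp-35 was at −1.39 ± 0.43. The list's median was −0.07 without N2-GC (adjusted p = 0.0351), −0.16 without ced-1-SS, and −0.58, −0.55 and −0.54 without dys-1-SS, dys-1-GC and ced-1-GC. The 47 histone genes had a median of −0.36 (−0.20 without ced-1-GC), which was −0.41 in the wild type, 0.10 in dys-1 and −0.61 in ced-1, with his-2 at −1.27 ± 0.29 (adjusted p = 0.0852). By limma 0 members of these lists passed over all genes, and adjusted over the list alone 0 neuropeptide genes and 1 histone gene passed, with 17 neuropeptide genes lower and 1 histone gene higher and 5 lower at an unadjusted p under 0.05. camera ranked both lists below other genes (adjusted p = 1.64e-09 and 6.79e-08, both adjusted p = 0.592 with an estimated correlation). The 23 heat shock genes had a median of −0.20, with the small heat shock gene hsp-16.2 at −1.28 ± 0.47 (camera adjusted p = 0.0145, adjusted p = 0.595 with an estimated correlation). This call was lost without ced-1-SS or N2-GC (adjusted p up to 0.201), the latter giving −0.07, and the median was −0.39 without ced-1-GC. The 42 neurotransmission genes had a median of −0.15, with −0.35, 0.00 and 0.05 in the wild type, dys-1 and ced-1 (camera adjusted p = 0.0364, adjusted p = 0.65 with an estimated correlation), a call lost without either of those arrays or N2-SS (adjusted p up to 0.72) and at 0.01 without N2-GC. By limma 0 heat shock and 0 neurotransmission genes passed over all genes or adjusted over the list alone, with 1 higher and 4 lower, and 2 higher and 1 lower, at an unadjusted p under 0.05.

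Of 175 cuticle collagens, 6 rose and 0 fell over all genes, and 36 rose and 13 fell adjusted over the list alone. In the fasting and lipid list hacd-1 was at 1.57 ± 0.30 (adjusted p = 0.0526). In the insulin list the insulin-like peptide gene ins-4 was at −1.46 ± 0.29 (adjusted p = 0.06). Among dauer markers the cuticlin gene cut-1 was at −1.98 ± 0.57 (adjusted p = 0.164) and col-2 at −1.49 ± 0.38 (adjusted p = 0.118). In these 3 lists limma passed 0 members over all genes, and 1, 1 and 2 adjusted over the list alone, with 3, 2 and 1 higher and 7, 3 and 2 lower at an unadjusted p under 0.05.

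Static and centrifuged flight worms shared the flight and differed in gravity and slightly in dose. T27E7.1 was 2.55 ± 0.23 log2 units higher in static flight (5.87-fold, limma adjusted p = 0.000591), with 2.26 to 2.79 in the 3 strains. It alone passed, and did so with each single array left out (adjusted p up to 0.0159). Next, without passing, were K06H6.2 at 2.08 ± 0.33, the infection response gene irg-4 at 1.49 ± 0.23, the C-type lectin gene clec-10 at 1.45 ± 0.23 and Y106G6E.3 at 1.24 ± 0.21 (each adjusted p = 0.0735). On the lower side were F56A4.2, at −2.40 to −1.61 in the 3 strains (adjusted p = 0.072), and the calcium-binding calexcitin gene cex-1 at −1.70 ± 0.28 (adjusted p = 0.0735). F49H6.5 was at −1.71 ± 0.35, F13H8.11 at −1.25 ± 0.26 and grd-13 at −1.02 ± 0.22 (each adjusted p = 0.104). At an unadjusted p under 0.05 there were 2394 genes. The count was 301 (283 higher, 18 lower) with weights estimated for each array, 3 with a trended and robust variance, 0 without variance moderation (2017 at an unadjusted p under 0.05) and 2 with only these conditions in the fit. It was 3 without ced-1-GC and 2 without ced-1-SC or N2-TC. By limma it was 0 when all arrays of the wild type or of ced-1 were left out (1687 and 1132 at an unadjusted p under 0.05).

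Sperm genes had a median of 0.59 over 48 members between the flown conditions, with 0.55 to 0.66 in the 3 strains. Examples were ssp-9 at 1.06 ± 0.26 and the sperm phosphatase gene gsp-4 at 1.04 ± 0.25. Among the 48 members limma passed 0 over all genes and 22 adjusted over the list alone, with 34 at an unadjusted p under 0.05. The 23 moulting genes had a median of 0.55, with the cuticlin gene cut-2 at 0.91 ± 0.25 and ptr-4, a patched-related gene, at 0.89 ± 0.27. Of these, 0 passed by limma over all genes and 5 adjusted over the list alone, with 11 at an unadjusted p under 0.05. The 175 collagens had a median of 0.37, with 0.37 in the wild type, 0.04 in dys-1 and 0.82 in ced-1. Among them 0 passed by limma over all genes, 32 were higher and 2 lower adjusted over the list alone, and 54 were higher and 9 lower at an unadjusted p under 0.05.

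The oocyte list (median 0.62), the cell cycle list (0.57) and the DNA repair list (0.29, with rad-54.L at 0.79 ± 0.23) also lay higher in static than in centrifuged flight. Neuropeptides (−0.50, with flp-5 at −1.40 ± 0.38) and dauer markers (−0.51, with cut-1 at −1.36 ± 0.57) lay lower. In each of these 5 lists limma passed 0 members over all genes and 0 adjusted over the list alone, with 7, 10, 7, 2 and 0 higher and 0, 0, 0, 18 and 5 lower at an unadjusted p under 0.05. These lists and the sperm, moulting and collagen lists kept their camera calls with each single array left out, but sizes moved. Without ced-1-SS the medians were 0.36 for the oocyte, 0.35 for the cell cycle, 0.15 for the DNA repair and −0.25 for the neuropeptide list. Without ced-1-SC they were 0.19 for the collagens, 0.36 for the moulting genes and −0.31 for the neuropeptides. The oocyte list was at 0.41 without N2-SC and the dauer list at −0.32 without dys-1-SC. Within strains neuropeptides were at −0.23 in the wild type, −0.13 in dys-1 and −1.19 in ced-1. On all arrays camera gave adjusted p = 1.74e-18 for the sperm genes and at most 0.00106, for the dauer markers. The sperm, moulting, collagen, neuropeptide and dauer lists had adjusted p = 0.592 with an estimated correlation, the cell cycle and DNA repair lists adjusted p = 0.595 with an estimated correlation and the oocyte list adjusted p = 0.613 with an estimated correlation.

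camera ranked 5 further lists lower in static than in centrifuged flight. The heat shock genes had a median of −0.23, with hsp-16.48 at −1.29 ± 0.42 (adjusted p = 0.00236, adjusted p = 0.592 with an estimated correlation). The insulin and dauer signalling genes were at −0.27, with ins-35 at −1.12 ± 0.29 (adjusted p = 0.00276, adjusted p = 0.592 with an estimated correlation). The ribosomal proteins were at −0.15 (adjusted p = 0.000555, adjusted p = 0.731 with an estimated correlation). The autophagy and lysosome genes were at −0.19, with the receptor gene sqst-1 at −0.73 ± 0.32 (adjusted p = 0.0145, adjusted p = 0.613 with an estimated correlation). The TGF-beta body size genes were at −0.25 (adjusted p = 0.0495, adjusted p = 0.592 with an estimated correlation). By limma 0 members of these lists passed over all genes or adjusted over the list alone, with 0, 1, 1, 0 and 1 higher and 8, 4, 2, 3 and 1 lower at an unadjusted p under 0.05. Without ced-1-SS the heat shock (−0.14, adjusted p = 0.051), ribosomal (−0.04, adjusted p = 0.3) and autophagy calls were lost. Without ced-1-SC the insulin (−0.17) and autophagy (−0.12) calls were lost (adjusted p up to 0.144), and without N2-SC the heat shock list was at −0.41. The TGF-beta call was lost without any 1 of the flown arrays, dys-1-GC, dys-1-TC or ced-1-TC (adjusted p up to 0.163).

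Worms flown in the 1 g centrifuge differed from the ground control in 7 genes. F26A1.8 fell by 3.58 ± 0.28 (12.0-fold, limma adjusted p = 0.000108), followed by K06H6.2 at −2.68 ± 0.33 (adjusted p = 0.012) and T27E7.1 at −1.64 ± 0.23 (adjusted p = 0.0222). dpy-1 was lower at −1.63 ± 0.25 (adjusted p = 0.0496), as was gmd-2, a GDP-mannose dehydratase gene, at −1.58 ± 0.24 (adjusted p = 0.042). C54F6.5 rose by 1.79 ± 0.23 (adjusted p = 0.0159) and F56A4.2 by 2.09 ± 0.29 (adjusted p = 0.0217). Next, without passing, were Y69E1A.5 at 1.31 (adjusted p = 0.168), the C-type lectin gene clec-143 at 1.41 and cex-1 at 1.44 (both adjusted p = 0.169). F26A1.8 and dpy-1 also fell in static flight. Independent lists of 4 and 5 genes would share 0.000999, though part of any excess may come from the shared ground control arrays. At an unadjusted p under 0.05 there were 1205 genes. The count was 12 with a trended and robust variance, 4 after quantile normalization, 3 without the strain factor or the transport control arrays and 1 without variance moderation or with only these conditions in the fit. It was 1 without N2-SC or N2-GC, 2 without ced-1-GC, 3 without dys-1-SC or ced-1-SC and 4 without dys-1-TC. F26A1.8 alone passed with each array left out (adjusted p up to 0.0028). The other 6 were lost without N2-SC or N2-GC, among others, and dpy-1 and gmd-2 without any single array (adjusted p up to 0.467).

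The 23 moulting genes had a median of −0.45 in centrifuged flight against the ground control, which was −0.06 in the wild type, −0.42 in dys-1 and −0.96 in ced-1. The list level of ced-1-GC, an array that stood apart, was 0.68, against 0.03 and 0.00 on the other ground control arrays. Members included cut-2 at −1.26 ± 0.25 and the hedgehog-related wrt-10 at −0.99 ± 0.26. By limma, 0 of 23 passed over all genes, while 10 were lower and 1 higher adjusted over the list alone, the same as at an unadjusted p under 0.05. The list was called by camera (adjusted p = 1.31e-08, adjusted p = 0.592 with an estimated correlation). The 31 oxidative stress genes had a median of 0.18, with the metallothionein gene mtl-1 at 1.27 ± 0.25 (adjusted p = 0.169) and the superoxide dismutase gene sod-3 at 1.16 ± 0.30. Of these 0 passed by limma over all genes and 2 adjusted over the list alone, with 4 at an unadjusted p under 0.05. They were called by camera too (adjusted p = 0.00708, adjusted p = 0.592 with an estimated correlation), and both lists kept their calls with each array left out. camera called 12 lists. The other 10, with adjusted p = 0.592 to adjusted p = 0.837 with an estimated correlation, were each lost without at least 1 centrifuge or ground control array (adjusted p up to 0.72). The vitellogenins, at 0.40, were lost without N2-GC (0.12, adjusted p = 0.72), dys-1-SC or ced-1-SC, and at 0.70 and 0.61 without dys-1-GC and ced-1-GC. Others were the collagens, at −0.20 with 0.14 in the wild type (adjusted p = 8.02e-05, adjusted p = 0.613 with an estimated correlation), lost without ced-1-SC (−0.06) or ced-1-GC (−0.08) (up to 0.501) and at −0.36 without N2-GC. Sperm genes were at −0.15 with 0.04 in the wild type (adjusted p = 0.00742, adjusted p = 0.675 with an estimated correlation), lost without dys-1-SC (−0.07) or dys-1-GC (−0.05) (up to 0.5) and at −0.26 without N2-GC. The histones, at −0.25 (adjusted p = 6.83e-06, adjusted p = 0.592 with an estimated correlation), were lost without ced-1-GC (−0.06, adjusted p = 0.0842).

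Of the 4 comparisons between single conditions, the one between the worms that never flew had the most passing genes. The ground control was compared with the transport control, which stayed in an incubator. The lysozyme genes lys-4, ilys-5 and lys-5 rose by 3.82 ± 0.27 (14.1-fold, limma adjusted p = 1.61e-05), 3.39 ± 0.32 and 2.98 ± 0.24. K06H6.2 rose by 3.88 ± 0.33, F26A1.8 by 3.74 ± 0.28 and the cuticle collagen genes col-88 and bli-6 by 3.11 ± 0.29 and 2.84 ± 0.33. W08E12.2, Y47D7A.15 and Y51H7C.13 each rose by 2.81, with errors of 0.25, 0.28 and 0.31. nspg-7.2, a nematode-specific peptide gene, fell by 5.08 ± 0.53 (33.9-fold, adjusted p = 0.00013). Also lower were Y57E12B.4 at −3.62 ± 0.28, mtre-1 at −3.44 ± 0.33, the infection response gene irg-5 at −3.40 ± 0.31 and T16G1.6 at −2.89 ± 0.40. The collagens col-183, col-164 and col-72 were at −3.65 ± 0.33, −3.31 ± 0.30 and −2.95 ± 0.28, and 5 of the 10 largest falls were col- genes. Each of these had an adjusted p of 0.00501 or less with any single array left out. In all 1069 genes passed, 619 higher and 450 lower, 931 of them past 2-fold and 1068 with the same sign in all 3 strains. The count was 698 without the strain factor, 549 with only these conditions in the fit and 370 without variance moderation. It was 1783 (781 higher, 1002 lower) without N2-GC, 634 without dys-1-GC, 591 without ced-1-GC, and 493 without ced-1-TC.

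Sperm genes rose together in the ground control relative to the transport control. Of 48 members 39 rose and 0 fell over all genes, and 43 rose adjusted over the list alone, with a median of 1.35 and 1.13 to 1.48 in the 3 strains. The major sperm protein gene msp-3 rose by 2.65 ± 0.27, gsp-4 by 2.11 ± 0.25, msp-142 by 2.04 ± 0.25 and msd-2 by 2.03 ± 0.23. The median was 1.40 over 30 msp- genes and 1.14 over the 18 other sperm genes. camera ranked the list above other genes (adjusted p = 4.51e-44, adjusted p = 0.592 with an estimated correlation). fry, which tests whether members move 1 way on balance, gave adjusted p = 0.00398.

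The vitellogenins had a median of 1.06 in the ground against the transport control, with 0.05 in the wild type, and vit-3 rose by 1.32 ± 0.30 (adjusted p = 0.018). Of 6 members 1 passed over all genes and 4 adjusted over the list alone (camera adjusted p = 0.000284, adjusted p = 0.592 with an estimated correlation). The oocyte list had a median of 0.42, ranging from −0.82 in the wild type to 1.13, and the meiotic cohesin gene rec-8 rose by 1.08 ± 0.26. Of 41 members 1 passed over all genes and 1 adjusted over the list alone (camera adjusted p = 0.000298, adjusted p = 0.742 with an estimated correlation). vit-3 and rec-8 were lost without the ground or transport control array of dys-1 or of ced-1 (adjusted p up to 0.18). The oocyte call was lost without dys-1-GC (0.25), dys-1-TC (0.18) or ced-1-TC (0.03, adjusted p up to 0.521), and its median was 0.74 without N2-GC and 1.04 without N2-TC. The cell cycle list was at 0.27, with −0.52 in the wild type (adjusted p = 0.0154, adjusted p = 0.8 with an estimated correlation). Among the 38 members limma passed 0 over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. Its call was lost without the ground or transport control array of either mutant, with a median of 0.13 without ced-1-GC and 0.00 without ced-1-TC (adjusted p = 0.988). It was 0.46 and 0.57 without N2-GC and N2-TC.

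Cuticle genes moved both ways. Of 175 collagens 44 rose and 22 fell over all genes, and 58 rose and 28 fell adjusted over the list alone. Their median was 0.32, or 0.19 without ced-1-GC (camera adjusted p = 1.29e-05, adjusted p = 0.613 with an estimated correlation). Of 23 moulting genes 3 rose over all genes, and 5 were higher and 2 lower adjusted over the list alone. cut-2 rose by 1.92 ± 0.25 and the protease gene nas-37, used in shedding the old cuticle, by 1.15 ± 0.22. The list's call (median 0.30 with 0.01 in the wild type, camera adjusted p = 0.00539, adjusted p = 0.592 with an estimated correlation) was lost without ced-1-GC (0.15, adjusted p = 0.0537) and at 0.48 and 0.52 without N2-GC and dys-1-TC.

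Of 18 dauer markers 4 fell over all genes and 8 adjusted over the list alone. The collagen gene col-2 fell by 2.25 ± 0.38 and scl-1 fell by 1.59 ± 0.24. The cuticlin genes cut-1 and cut-6 were lower at −2.56 ± 0.57 and −1.97 ± 0.30, of which cut-1 was lost without dys-1-GC, N2-TC or ced-1-TC (adjusted p up to 0.107). The list's median was −0.50, or −0.23 without ced-1-TC (camera adjusted p = 0.0015, adjusted p = 0.592 with an estimated correlation). In the insulin and dauer signalling list, at a median of −0.57 with −0.10 in the wild type, 5 of 29 fell over all genes and 6 adjusted over the list alone. Among them ins-35 fell by 1.38 ± 0.29, and the kinase gene pdk-1 fell by 1.24 ± 0.26. Both were lost without ced-1-GC or ced-1-TC, ins-35 also without dys-1-GC and pdk-1 without dys-1-TC (adjusted p up to 0.0952). The list was called by camera (adjusted p = 0.000694, adjusted p = 0.592 with an estimated correlation).

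Neuropeptide and neurotransmission lists were ranked lower in the ground than in the transport control. Differences between the strain values, each from 1 array per condition, were not tested. Of 107 neuropeptide genes 13 fell and 2 rose over all genes, and 20 fell and 2 rose adjusted over the list alone. The median of −0.67 was 0.22 in the wild type, −0.93 in dys-1 and −1.36 in ced-1, and it was −1.07 without N2-GC and −0.40 without ced-1-TC. nlp-68 fell by 2.07 ± 0.33 and nlp-39 fell by 1.87 ± 0.35. Of 42 neurotransmission genes, at −0.48 with 0.01 in the wild type, −0.74 in dys-1 and −0.65 in ced-1, 2 fell over all genes and 3 adjusted over the list alone. Among them was unc-25, which makes the enzyme for GABA synthesis, which fell by 1.47 ± 0.35 and was lost without ced-1-GC, dys-1-TC or ced-1-TC (adjusted p up to 0.17). Of 12 hypoxia response genes, at −0.54, 2 fell over all genes and 5 adjusted over the list alone. nhr-57, a target of the hypoxia factor, fell by 1.60 ± 0.32 and was lost without dys-1-GC, ced-1-GC or ced-1-TC (adjusted p up to 0.067). Of 33 autophagy and lysosome genes, at −0.37, 1 rose over all genes and 1 adjusted over the list alone. This was the proton pump gene vha-6, at 1.07 ± 0.25, lost without dys-1-GC, N2-TC or dys-1-TC (adjusted p up to 0.133). camera ranked these 4 lists below other genes, with adjusted p = 1.03e-08, 3.86e-05, 0.000387 and 0.000447. Each had adjusted p = 0.592 with an estimated correlation.

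Of 186 xenobiotic detoxification genes, at a median of −0.16, 13 fell and 2 rose over all genes, and 16 fell and 2 rose adjusted over the list alone. The cytochrome P450 gene cyp-33C1 fell by 1.91 ± 0.34. The camera call (adjusted p = 0.0148, adjusted p = 0.592 with an estimated correlation) was lost without N2-GC (adjusted p = 0.12). The 14 dystrophin complex genes were at −0.45 (−0.07 in the wild type), with the dys-1 gene at −0.81 ± 0.26 (adjusted p = 0.0919). By limma, 0 of 14 passed over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05. Their camera call (adjusted p = 0.0233, adjusted p = 0.592 with an estimated correlation) was lost without dys-1-GC (−0.28), dys-1-TC (−0.21) or ced-1-TC (adjusted p up to 0.104), and the median was −0.28 without ced-1-GC.

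In the lists that camera did not call between the ground and transport controls, single members changed. Of 334 innate immunity genes 17 rose and 20 fell over all genes, and 18 rose and 23 fell adjusted over the list alone. Of 31 oxidative stress genes the metallothionein gene mtl-2 rose by 1.66 ± 0.30 and 2 members fell over all genes, against 1 higher and 6 lower adjusted over the list alone. Of 47 histone genes his-70 rose by 1.34 ± 0.25 and the linker histone gene his-24 fell by 1.32 ± 0.26, with the same counts adjusted over the list alone. his-24 was lost without dys-1-GC or ced-1-TC (adjusted p up to 0.0523). Over all genes 1 of 58 DNA repair genes rose (polq-1 by 0.88 ± 0.22), as did 1 of 32 apoptosis and engulfment genes (the nuclease gene crn-6 by 0.88 ± 0.23). The only muscle gene of 46 to pass was the pharyngeal myosin gene myo-2, which fell by 1.00 ± 0.27. Of 17 TGF-beta body size genes 1 rose (the collagen gene lon-3 by 1.19 ± 0.30), and of 38 respiratory chain genes 1 rose (the cytochrome c gene cyc-2.2 by 1.29 ± 0.30). Of 23 heat shock genes 1 rose (hsp-16.2 by 1.83 ± 0.47) and 1 fell, and of 50 fasting and lipid genes 1 rose (lbp-5 by 0.99 ± 0.25) and 1 fell. Adjusted over the list alone, 0 DNA repair, apoptosis and muscle genes passed by limma, with 4, 1 and 3 higher and 1, 3 and 6 lower at an unadjusted p under 0.05. The other 4 of these lists had the same counts adjusted over the list alone. These last 7 named calls were each lost without dys-1-GC and without ced-1-TC, and each of the 12 arrays ended at least 1 of them (adjusted p up to 0.264). Among 75 ribosomal protein genes limma passed 0 over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05.

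The flown pair, static and centrifuged together, was compared with both controls together. Collagens led in both directions. col-19 was higher by 3.11 ± 0.26 (SE, 6 arrays on each side, 8.62-fold, limma adjusted p = 3.54e-05), col-129 by 2.89 ± 0.19, col-143 by 2.86 ± 0.26 and spig-20 by 2.46 ± 0.20. Of the 10 largest rises 9 were col- genes. col-43 was lower at −2.79 ± 0.52, the hedgehog-related grl-20 at −2.64 ± 0.40, cut-1 at −2.58 ± 0.40 and col-37 at −2.41 ± 0.30. col-84 was at −2.33 ± 0.33, mtre-1 at −2.23 ± 0.23 and grl-25 at −2.14 ± 0.22, and 6 of the 10 largest falls were col- genes. In all 1189 genes passed, 857 higher and 332 lower, each with the same sign in all 3 strains, and 505 were past 2-fold. The comparison is not specific to flight. Against the ground control alone 8 genes passed (5 higher, 3 lower) and against the transport control alone 2506 (1416 higher, 1090 lower). Setting static flight and ground control against centrifuged flight and transport control gave 1348. lys-4 and ilys-5, higher by 1.83 ± 0.19 and 1.55 ± 0.22 in the flown pair, were at −0.08 (adjusted p = 0.958) and −0.15 (adjusted p = 0.923) against the ground control alone. The count was 440 without variance moderation, 773 without N2-SS, 646 without ced-1-SS, 775 without dys-1-SC and 740 without ced-1-TC.

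**Figure D3:**
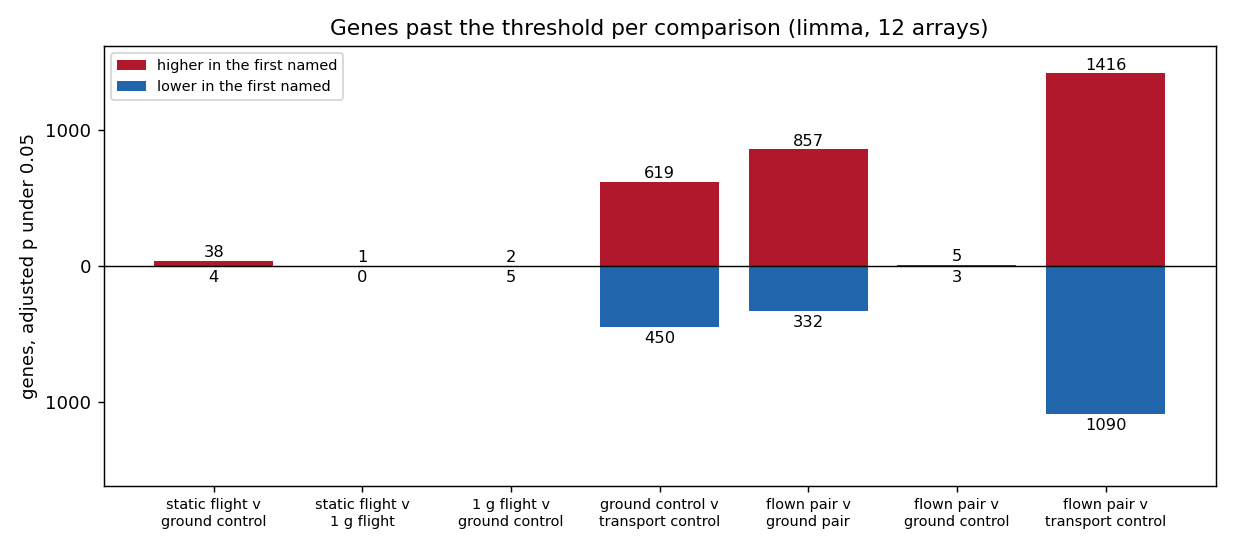
Number of genes with an adjusted p under 0.05 (y axis, limma), higher (bars upward) or lower (bars downward) in the first named condition, for 5 comparisons and for the flown pair against each control alone. The ground and transport controls differed in 619 higher and 450 lower genes, and the flown pair differed from the ground control alone in 5 higher and 3 lower.

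Sperm genes were higher in the flown pair, 38 of 48 over all genes and 41 adjusted over the list alone, with a median of 0.81, msd-2 at 1.90 ± 0.16 and msd-1 at 1.81 ± 0.17. camera called the list (adjusted p = 9.8e-34, adjusted p = 0.592 with an estimated correlation), and fry gave adjusted p = 0.00398. Of 6 vitellogenins 4 rose over all genes and 5 adjusted over the list alone, with vit-6 at 1.70 ± 0.27. They were called by camera (adjusted p = 1.02e-06, adjusted p = 0.592 with an estimated correlation). In the oocyte list 4 of 41 rose over all genes and 17 adjusted over the list alone, with puf-3 at 1.19 ± 0.24. Its median was 0.54, or 0.82 without N2-TC, and it too was called (adjusted p = 9.05e-08, adjusted p = 0.613 with an estimated correlation). Of 58 DNA repair genes 6 rose over all genes and 7 adjusted over the list alone, at a median of 0.27 (camera adjusted p = 4.1e-06, adjusted p = 0.592 with an estimated correlation). The base excision repair gene exo-3 rose by 0.96 ± 0.21, rad-54.L by 0.77 ± 0.17 and the poly(ADP-ribose) polymerase gene parp-1 by 0.80 ± 0.19. All 3 were lost without ced-1-SS, and exo-3 and parp-1 also without ced-1-TC. parp-1 was further lost without N2-SS, dys-1-SC, ced-1-SC or N2-GC (adjusted p up to 0.082). Of 38 cell cycle genes 5 rose over all genes and 5 adjusted over the list alone (camera adjusted p = 8.13e-06, adjusted p = 0.613 with an estimated correlation). The replication helicase gene mcm-3 rose by 0.90 ± 0.20, a call lost without ced-1-SS (adjusted p = 0.0563).

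Of 107 neuropeptide genes 10 were lower in the flown pair over all genes and 22 adjusted over the list alone, with nlp-64 at −1.13 ± 0.22. Their median was −0.45, or −0.29 without N2-GC (camera adjusted p = 1.09e-13, adjusted p = 0.592 with an estimated correlation). Of 29 insulin and dauer signalling genes 3 were lower over all genes and 3 adjusted over the list alone, with ins-4 at −1.53 ± 0.20 and ins-35 at −1.10 ± 0.21. The list's call (median −0.15, camera adjusted p = 0.0154, adjusted p = 0.592 with an estimated correlation) was lost without N2-SC or N2-GC (adjusted p up to 0.061). Its median was −0.29 without N2-SS and −0.08 without ced-1-SS, and −0.34, −0.23 and −0.27 without ced-1-SC, ced-1-GC and N2-TC. Of 47 histone genes 2 were lower and 1 higher over all genes, and 5 lower and 1 higher adjusted over the list alone (median −0.36, camera adjusted p = 5.71e-07, adjusted p = 0.592 with an estimated correlation). Of 334 innate immunity genes 14 were higher and 23 lower over all genes, and 18 higher and 28 lower adjusted over the list alone, with the lectin gene clec-174 at −1.81 ± 0.20. Of 46 muscle genes 1 was higher over all genes and 0 adjusted over the list alone by limma, with 6 higher and 2 lower at an unadjusted p under 0.05, and the body wall myosin gene myo-3 was at 0.64 ± 0.20 without passing (adjusted p = 0.0817). By limma 0 apoptosis, heat shock, ribosomal and dystrophin complex genes passed over all genes or adjusted over the list alone, with 1, 2, 2 and 0 higher and 1, 0, 0 and 2 lower at an unadjusted p under 0.05. The dystrophin complex list was at −0.22 (camera adjusted p = 0.0205, adjusted p = 0.592 with an estimated correlation), a call lost without N2-GC (−0.14) or dys-1-TC (adjusted p up to 0.0602).

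A test of any difference among the 4 conditions passed 1648 genes, with 4576 at an unadjusted p under 0.05. That count was 513 without variance moderation, 989 without N2-SS, 971 without ced-1-SS, 1012 without dys-1-TC and 847 without ced-1-TC.

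**Figure D4:**
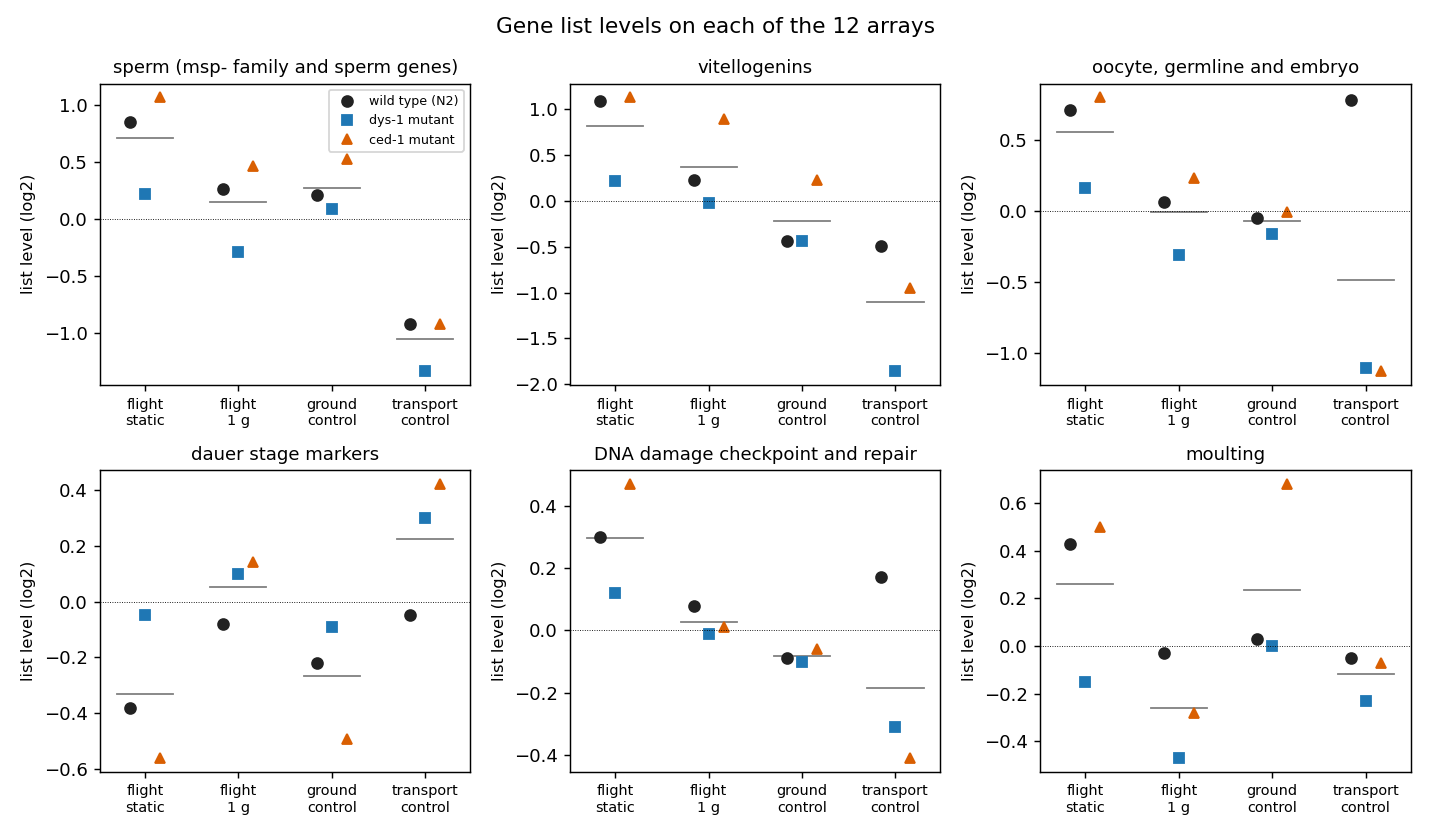
Level of 6 gene lists on each of the 12 arrays, as the list level in log2 units relative to the average of the 12 arrays (y axis) by condition (x axis); points are single arrays, marker and colour give the strain, and grey lines are means of 3 arrays. The sperm list lies lowest in the transport control of each strain, at −0.92 in the wild type, −1.34 in dys-1 and −0.92 in ced-1.

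The dys-1 mutant was compared with the wild type across the 4 conditions, and no gene passed. acs-2, a fatty acid activation gene, was at 3.31 ± 0.66 (SE, 4 arrays per strain, limma adjusted p = 0.115) and icl-1, a glyoxylate cycle gene, at 2.09 ± 0.33 (adjusted p = 0.0826). F46C5.1 was at 2.57 ± 0.41, the receptor gene dmsr-2 at 1.24 ± 0.20, Y46H3C.7 at 1.48 and nssp-34 at 1.45 (each adjusted p = 0.0826). Lower in dys-1 were T04C9.3 at −1.35, F16H11.2 at −1.34 and mltn-3 at −1.17 ± 0.20 (each adjusted p = 0.0826), col-175 at −1.17 (adjusted p = 0.0957) and Y53G8AM.2 at −1.04 (adjusted p = 0.0971). By limma 0 genes passed, with 2976 at an unadjusted p under 0.05, also 0 without variance moderation, and 64 with array weights. Without N2-GC 329 genes passed, 4 without dys-1-GC, 3 without ced-1-TC and 142 without all ground control arrays.

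Heat shock genes had a median of 0.53 in dys-1 against the wild type (0.34 without dys-1-SS), with the small heat shock genes hsp-12.6 at 2.08 ± 0.58 and hsp-16.48 at 1.61 ± 0.36. By limma, 0 of 23 passed over all genes and 10 adjusted over the list alone, with 10 higher and 1 lower at an unadjusted p under 0.05. They were called by camera (adjusted p = 5.71e-07, adjusted p = 0.592 with an estimated correlation). The oocyte list had a median of −0.82 (−0.31 without N2-TC, adjusted p = 9.07e-06), with the embryonic RNA-binding gene pos-1 at −1.43 ± 0.39 and the eggshell proteoglycan gene cpg-2 at −1.31 ± 0.37. Among the 41 members limma passed 0 over all genes and 15 adjusted over the list alone, with 23 at an unadjusted p under 0.05 (camera adjusted p = 4.5e-12, adjusted p = 0.592 with an estimated correlation). The hypoxia list had a median of 0.40, with nhr-57 at 1.17 ± 0.27 and egl-9 at 0.81 ± 0.21. Among the 12 members limma passed 0 over all genes and 3 adjusted over the list alone, with 6 at an unadjusted p under 0.05 (camera adjusted p = 0.000694, adjusted p = 0.592 with an estimated correlation). The dystrophin complex list had a median of 0.31, with the calcium channel gene egl-19 at 0.91 ± 0.28 and the syntrophin gene stn-2 at 0.73 ± 0.21. By limma, 0 of 14 passed over all genes and 2 adjusted over the list alone, with 3 higher and 1 lower at an unadjusted p under 0.05. Its call (camera adjusted p = 0.00748, adjusted p = 0.592 with an estimated correlation) was lost without N2-TC (0.20, adjusted p = 0.0564).

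Further lists lay lower in dys-1. Cuticle collagens had a median of −0.40, histones −0.54, cell cycle genes −0.43 and sperm genes −0.39. Without N2-TC the histones were at −0.29 and the cell cycle genes at −0.17. By limma 0 passed over all genes while 25, 0, 4 and 0 were lower adjusted over the list alone, with 59, 24, 13 and 20 lower and 6, 0, 0 and 0 higher at an unadjusted p under 0.05. camera called each (adjusted p = 4.04e-08 or lower, adjusted p = 0.592 with an estimated correlation). Of 50 fasting and lipid genes, at a median of 0.15, 0 passed by limma over all genes, and 6 were higher and 1 lower adjusted over the list alone, with 10 higher and 2 lower at an unadjusted p under 0.05. This call (camera adjusted p = 0.00693, adjusted p = 0.592 with an estimated correlation) was lost without N2-GC or dys-1-GC (0.05) (adjusted p up to 0.0988). Its median was 0.25 and 0.26 without N2-SC and dys-1-SC, and 0.03 and 0.09 without N2-TC and dys-1-TC.

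In the ced-1 mutant no gene passed against the wild type. mltn-3 was at −1.10 ± 0.20 and the chemoreceptor gene srx-93 at 1.25 ± 0.22 (SE, 4 arrays per strain, both limma adjusted p = 0.739). Next came Y105C5B.5 at 0.98, col-105 at 0.94, the peroxidase gene hpx-2 at 0.87 and E03H12.7 at 0.84, and lower Y56A3A.9 at −1.37, F22D3.5 at −1.17, skr-21 at −1.11 and F22E5.20 at −1.05 (adjusted p 0.89 to 0.908). By limma 0 genes passed, with 1059 at an unadjusted p under 0.05, and 0 under each alternative run. The apoptosis and engulfment list had a median of −0.13, with the GTPase gene ced-10 at −0.56 ± 0.21 and ced-1 itself at −0.18 ± 0.19. Among the 32 members limma passed 0 over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0145, adjusted p = 0.592 with an estimated correlation). Collagens had a median of 0.22, with col-158 at 1.06 ± 0.35, and sperm genes 0.23, with msd-2 at 0.64 ± 0.20. In these lists 0 passed by limma over all genes or adjusted over the list alone, with 14 collagens higher and 2 lower, and 3 sperm genes higher, at an unadjusted p under 0.05 (camera adjusted p = 1.64e-09 and 1.02e-06, both adjusted p = 0.592 with an estimated correlation). The collagen median was 0.36 without ced-1-SC, 0.10 without N2-GC and 0.12 without ced-1-GC, and the sperm median 0.14 without N2-GC.

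The oocyte list of ced-1 was at −0.39, with puf-5 at −0.67 ± 0.42 (camera adjusted p = 9.05e-08, adjusted p = 0.613 with an estimated correlation). The DNA repair list was at −0.06 (camera adjusted p = 0.0259, adjusted p = 0.731 with an estimated correlation). Without N2-TC these medians were 0.06 (adjusted p = 0.283) and 0.01 (adjusted p = 0.836), and puf-5 was at 0.01 (adjusted p = 0.995). Both lists were also lost without ced-1-TC, at −0.13 and 0.01 (adjusted p up to 1). Without N2-GC they were at −0.59 and −0.13, and the DNA repair list was at −0.12, −0.14 and −0.11 without N2-SS, ced-1-SS and N2-SC. By limma 0 oocyte and 0 DNA repair genes passed over all genes or adjusted over the list alone, with 1 each at an unadjusted p under 0.05.

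Whether the flown pair differed from the control pair by another amount in a mutant than in the wild type was tested as an interaction. For dys-1 the lysozyme gene lys-3 was at 2.88 ± 0.46 (2 arrays per strain and side, limma adjusted p = 0.463), C23H5.11 at 3.35 ± 0.53 and ZK218.3 at 3.86 ± 0.62 (both adjusted p = 0.463). For ced-1 the collagen gene col-165 was at −1.58 ± 0.35 and the meiotic gene msh-4 at 1.90 ± 0.44 (both adjusted p = 1). By limma 0 genes passed for dys-1, with 458 at an unadjusted p under 0.05, and 0 for ced-1, with 617. In simulated data a 4-fold interaction was recovered for 4% of changed genes for dys-1 and 20% for ced-1. Such a difference was mostly not detectable.

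Within each strain static flight was also set against the ground control with 1 array on each side, so these differences have no replicate check and no test. In the wild type 1172 genes were at least 2-fold higher and 900 lower, led by col-95 at 3.55 and T22F3.11 at −3.64. In dys-1 397 were higher and 461 lower, led by Y59A8B.26 at 3.97 and F45D11.1 at −3.84, and in ced-1 1244 were higher and 847 lower, led by col-95 at 3.41 and col-43 at −5.09. hsp-12.6 was at 3.09 in dys-1, and F26A1.8 was at −3.49, −3.66 and −4.52 in the wild type, dys-1 and ced-1.

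Strains were compared across genes, which are not independent replicates. For static flight against the ground control, Pearson's r was 0.33 between the wild type and ced-1 and 0.12 for both other pairs. For centrifuged flight it was −0.07 to 0.08. For the ground against the transport control it was 0.54 between the mutants, and 0.25 (dys-1) and 0.27 (ced-1) with the wild type. No pair shares an array, and simulated r (at most 0.01) sets no chance level for dependent genes. Static flight changes in a strain and ground against transport changes in another gave 0.01 to 0.40, so r is not specific to flight.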

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

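The tests of the sperm pattern, of the dys-1 pattern by normalization and stage axis and of the ground control pattern by moulting and run day, the interactions without the transport control and the outlier tests of lists other than sperm, oocyte, vitellogenin and DNA repair were chosen after the result was seen. The others were chosen before.

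Differences between strains in the response of the flown pair were tested as interactions, and 16 gene lists were called by camera at the preset correlation. Among single genes 0 passed by limma, with 458 (dys-1) and 617 (ced-1) at an unadjusted p under 0.05. In dys-1 relative to the wild type, the muscle list had a median difference of −0.37 (camera adjusted p = 1.34e-06), with the body wall myosin gene myo-3 at −1.13 ± 0.38 and the paramyosin gene unc-15 at −1.10 ± 0.36. The histone list was at 0.51 (adjusted p = 1.68e-08), the oocyte list at 0.49 (0.00064), neuropeptides at 0.46 (0.00112) and sperm genes at −0.36 (0.00742). The 9 dys-1 lists had adjusted p = 0.592 to adjusted p = 0.837 with an estimated correlation. The others were moulting genes at −0.43 (adjusted p = 0.00751), cuticle collagens at −0.26 (0.00171), innate immunity genes at −0.15 (0.0444) and ribosomal proteins at 0.14 (0.0144).

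Of these 9 dys-1 lists, only the muscle list kept its call with each array left out (adjusted p up to 0.00338) and without all transport control arrays (−0.35, adjusted p = 0.0118), both at the preset correlation (on all arrays adjusted p = 0.592 with an estimated correlation). Without the transport control, the oocyte list turned to −0.44 (adjusted p = 0.00182), histones were at 0.18 (0.106) and ribosomal proteins at 0.16 (0.094), while neuropeptides were at 1.07, sperm genes at −0.53, collagens and moulting genes both at −0.43 and innate immunity genes at −0.22. Histones were at 0.85 without N2-GC and 0.25 without N2-TC. The oocyte call was lost without dys-1-SS (0.28), N2-SC (0.20), N2-TC (0.14) or dys-1-TC (0.02), and was at 0.83 without N2-SS or N2-GC and 0.97 without dys-1-GC. The sperm call was lost without N2-SS (−0.05), dys-1-SC (−0.12), dys-1-GC (0.39) or N2-TC (0.22), and was at −0.64, −0.65, −0.95 and −1.12 without dys-1-SS, N2-SC, N2-GC and dys-1-TC. Collagens were lost without N2-SS or dys-1-GC (both −0.04), and at −0.45, −0.44 and −0.54 without N2-SC, N2-GC and dys-1-TC. Moulting genes were lost without N2-SS (−0.25), dys-1-SC (−0.24), dys-1-GC or N2-TC (adjusted p up to 0.123). Neuropeptides were lost without N2-SS or dys-1-GC (0.09), and at 0.95 without dys-1-TC. Innate immunity genes were lost without N2-SC, dys-1-SC, N2-GC or dys-1-GC (−0.08 for the last, adjusted p up to 0.373), and ribosomal proteins without N2-SS or dys-1-TC (adjusted p up to 0.133).

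In ced-1 relative to the wild type, the oocyte list had a median difference of 0.99 (camera adjusted p = 1.02e-10), with the eggshell gene cpg-3 at 1.73 ± 0.79 and the germline regulator gld-1 at 1.62 ± 0.68. The cell cycle list was at 0.47 (adjusted p = 0.000114), with cyb-2.1 at 1.75 ± 0.85, and the DNA repair list at 0.35 (0.000591), with parp-2 at 1.23 ± 0.44. The 7 ced-1 lists had adjusted p = 0.592 to adjusted p = 0.824 with an estimated correlation. The others were cuticle collagens at −0.41 (adjusted p = 1.41e-05), moulting genes at −0.31 (0.0245), xenobiotic genes at −0.16 (0.0358) and ribosomal proteins at −0.11 (0.0281). Each named member had limma adjusted p = 1.

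The levels behind the 3 germline-related ced-1 lists differed in the transport control, where the wild type and ced-1 stood at 0.78 and −1.13 for oocyte, 0.36 and −0.78 for cell cycle and 0.17 and −0.41 for DNA repair genes. Their ground control oocyte levels were −0.05 and −0.01. Without all transport control arrays these lists were at 0.10 (adjusted p = 0.957), −0.10 (0.35) and 0.12 (0.881), xenobiotic genes at −0.06 (0.118) and ribosomal proteins at 0.02 (0.592), while collagens were at −0.70 (7.58e-11) and moulting genes at −0.65 (0.00713). With single arrays left out, the oocyte list was at 0.52 without ced-1-TC (adjusted p = 0.0373) and 1.59 without ced-1-GC. The cell cycle call was lost without ced-1-SS (0.17), N2-TC (0.30) or ced-1-TC (0.24), and was at 0.73, 0.31, 0.89 and 0.86 without N2-SS, N2-SC, ced-1-SC and ced-1-GC. The DNA repair call was lost without ced-1-SS (0.09), N2-TC or ced-1-TC (0.20), and was at 0.54, 0.18 and 0.63 without N2-SS, N2-SC and ced-1-SC. Collagens were lost without ced-1-SC or ced-1-GC (both −0.12), and at −0.20, −0.88, −0.65 and −0.67 without N2-SS, ced-1-SS, N2-SC and ced-1-TC. Moulting genes were lost without N2-SS (−0.19), ced-1-SC (−0.03), ced-1-GC (−0.16) or N2-TC (−0.10), and at −0.66, −0.56, −0.53 and −0.73 without ced-1-SS, N2-SC, N2-GC and ced-1-TC. Xenobiotic genes were lost without ced-1-SS, N2-SC or N2-GC (each −0.06) or ced-1-TC (0.00), and at −0.25 without N2-TC. Ribosomal proteins were lost without ced-1-SS (0.08), N2-SC (−0.07), N2-GC, N2-TC or ced-1-TC (0.02), and at −0.26 and −0.24 without ced-1-SC and ced-1-GC.

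Array means, the dys-1 and ced-1 levels and all 25 list levels were searched in each strain for an outlying array. Of 84 tests 5 passed Dixon's critical value, and chance passes about 1 in 20. dys-1-TC was at 0.62 for the dystrophin complex (next 0.13), 0.55 for insulin signalling (0.09) and 0.77 for neurotransmission genes (0.05), dys-1-SC at 0.46 for heat shock genes (0.35) and N2-SS at 0.43 for moulting genes (0.03).

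Sperm genes were higher in the ground than in the transport control. Against the ground control their median was 0.38 in static and −0.15 in centrifuged flight. Distribution differences left by RMA are argued against by a median of 1.46 after quantile normalization. RMA itself was not tested. Signal shared by near-identical msp- probes is argued against by a median of 1.14 over sperm genes outside that family. A different mix of developmental stages stays open: sperm, vitellogenin and oocyte lists were higher and dauer markers lower in 2 of 3 strains, while in the wild type sperm genes were at 1.13 with vitellogenins at 0.05 and oocyte genes at −0.82. A difference between housing in flight hardware and in an incubator was not tested.

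The dys-1 mutant had the fewest genes past 2-fold between static and centrifuged flight, 397 against 1443 in the wild type and 2700 in ced-1, with 1 array on each side and no test of the difference. Distribution differences are argued against by 336 genes after quantile normalization, against 1469 and 2714. A stage axis shared by the other strains stays open. Its removal left 391 against 1199 and 2354, but it held only 2.8% to 9.6% of the variance, too little to decide. Lower noise of the dys-1 arrays could account for part, since the spread of its dimmest genes was 0.78 of that of the other strains against 0.65 over all genes, and this stays open. A smaller response of the mutant to gravity was not separable from these with 1 array per cell of the design.

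F26A1.8 was high in the 3 ground control arrays, at 10.4 or above, and at 7.53 or below in the other 9. Of 64 sets of 1 array per strain, 3 had as many genes at least 2-fold above all other arrays. These were the ground control, the transport control (44) and 1 mixed set (1), which argues against chance for this gene. The moulting phase of the ground control worms stays open, with the moulting list at −0.04 in static flight and −0.45 in centrifuged flight against the ground control. The run on other days also stays open, since run and condition cannot be told apart.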

How the results depend on the processing

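The fits by transcript feature, without the transport control condition (interactions included), and of the flown pair against each control alone, and the permutation within conditions, were chosen after seeing the data. Where a value moved, the cause was not tested, except that fewer arrays or no shared variance lower the power of a fit. The arrays limit precision, and without background or detection values the signal over background of a gene is not known.

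Genes passing were counted under each setting. For static flight against ground control the 42 became 6 (3 higher, 3 lower) after quantile normalization, 9 (6 higher, 3 lower) after median centring, 116 (109 higher, 7 lower) with an offset of 50, 0 without variance moderation (limma's linear model, 2117 at an unadjusted p under 0.05), 1 with no strain factor (no replicate block), 5 with only the compared conditions and 2 without the transport control condition. Leaving out a strain or an array gave 1 to 59. For static against centrifuged flight the 1 became 3 with a trended and robust variance, 0 without moderation (2017 at an unadjusted p under 0.05), 301 with array weights and 2 with only the compared conditions, and 0 to 3 with a strain or array left out (limma, 1687 and 1132 at an unadjusted p under 0.05 without the wild type and without ced-1, both with 0). For centrifuged flight against ground control the 7 became 12 with a trended and robust variance, 4 after quantile normalization, 1 without moderation, 3 with no strain factor (no replicate block), 1 with only the compared conditions and 3 without the transport control condition, and 1 to 7 with a strain or array left out.

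For the ground against the transport control the 1069 became 370 without moderation, 698 with no strain factor (no replicate block) and 549 with only the compared conditions, and 347 to 1783 with a strain or array left out. For the flown against the control pair the 1189 became 440 without moderation, 505 with a 2-fold minimum, 8 against the ground control alone and 2506 against the transport control alone, and 485 to 1622 with a strain or array left out. For any condition effect the 1648 became 513 without moderation, and 570 to 2214 with a strain or array left out. For dys-1 against wild type the 0 by limma (2976 at an unadjusted p under 0.05) became 64 with array weights, 142 without the ground control condition, and 0 to 329 with a strain or array left out. ced-1 against wild type and both interactions stayed at 0 by limma in each alternative run (1059, 458 and 617 at an unadjusted p under 0.05). The fit with no strain factor changed no other count by over 1.5 times. Of the gene list calls, 105 by camera became 0 with an estimated correlation and 2 by fry.

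Without the ced-1 transport control array the cell cycle list in the ground against the transport control was at 0.00 (0.00 to 0.57 over single arrays left out). Without the wild-type transport control array the DNA repair and oocyte lists of ced-1 against wild type were at 0.01 (range −0.14 to 0.01) and 0.06 (−0.59 to 0.06). Among the dys-1 interactions, the sperm list was at 0.39 without the dys-1 ground control and 0.22 without the wild-type transport control array (range −1.12 to 0.39), and the oocyte list at 0.02 without the dys-1 transport control array (0.02 to 0.97) and −0.44 without that condition. Among those of ced-1, ribosomal proteins were at 0.08 without the ced-1 static flight array (−0.26 to 0.08) and the cell cycle list at −0.10 without the transport control condition. The mutant difference of the dys-1 transcript was −0.07 without the dys-1 transport control array (range −0.07 to 0.40). lys-4 and ilys-5 in the flown pair were at −0.08 and −0.15 against the ground control alone, and puf-5 in ced-1 against wild type was at 0.09 without the transport control condition and 0.01 without the wild-type transport control array (range −0.95 to 0.09). Of 1801 alternatives over 105 list calls, 1410 kept direction and side of the threshold, 382 were weaker and 9 reversed, and of 7114 alternatives over 286 named genes by comparison, 6032 kept both, 982 were weaker, 96 stronger and 4 reversed.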

Other observations

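The tests of other groupings of the arrays were chosen before the results were seen, the pairing of conditions after.

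Each condition was also searched for genes at least 2-fold above or below all 9 other arrays. The transport control had 44 genes above and 107 below, the ground control 1 above and 0 below, and the flown conditions 0 and 0. No adjusted p was computed.

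For each comparison of 3 arrays with 3, the arrays were regrouped in all 10 ways, which are too few for a share under 0.05. Static flight against ground control gave 42 genes and at most 0 in any other split, and static against centrifuged flight 1 and 0. Centrifuged flight against ground control gave 7 and 0, and ground against transport control 1069 and 0. For any difference among conditions, 1 of 100 regroupings within strains gave as many as the real 1648 (highest other 1205), which argues against chance. For the mutants the real count was 0 by limma, with 2976 (dys-1) and 1059 (ced-1) genes at an unadjusted p under 0.05. All 35 splits of the 8 arrays gave as many by construction. Other splits gave up to 4 and 2.

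For the flown pair against the control pair, 3 of 100 regroupings within strains gave as many as the real 1189 (highest other 1279). These mix the conditions within each side between strains, and the count moves with that: static flight and ground control against centrifuged flight and transport control gave 5 mixed but 1348 with whole conditions. Chance is therefore not excluded here. No test here separates flight hardware, transport and stage.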
